A study of Mus musculus with 4 samples.

How the data were processed

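RNA was measured in cells sorted from the gut of juvenile mice of the FVB/N strain. The mice carried a transgene in which Plp1, the gene of the myelin protein proteolipid protein, drives the green fluorescent protein GFP. Ileum and colon were broken up with enzymes and the cells were sorted by fluorescence, per the labels' protocols. The 4 libraries formed 4 groups, 1 each for GFP-positive and GFP-negative cells of the ileum and of the colon. Each library was made from the pooled cells of 3 animals, with 10 ng of RNA and a low-input kit. Paired reads of 100 bases were taken on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, Bowtie2, TopHat2, Cufflinks and Cuffdiff with the build mm10, without roles or settings.

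The deposited table held 1 FPKM column for GFP-positive cells and 1 for GFP-negative cells, per the file headers, with no column for ileum or colon. FPKM values are fragment counts scaled by transcript length and by the number of mapped fragments. How the libraries of the 2 gut regions were combined is not given in the sources used here. Both columns are therefore printed as the authors' values, without SD or n. The authors' table also gave a log2 fold change, a p-value, a q-value, a test status and a significance call for each gene, per the file headers. The deposited log2 fold change was the log2 ratio of the 2 FPKM columns within 0.01 in all 12602 tested genes above 0 in both columns. The deposited calls were the genes with a q-value under 0.05. The model behind the p-values, and what spread it used with these libraries, is not given in the sources used here.

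The table listed 23284 genes, of which the authors tested 12803. Another 10313 were marked as not tested, 150 as low data, 17 as failed and 1 as high data. An FPKM of 0 can be a failed estimate: Malat1, an abundant nuclear RNA, stood at 1891 FPKM in GFP-negative cells and was listed at 0 in GFP-positive cells with the status of high data. A gene at 0 is therefore only said to be listed at 0. In 4285 rows the interval given was shared with another row, so reads of overlapping genes could be divided between them; none of the authors' called genes was among these rows. Whether the counting used the strand is not given in the sources used here. The small nucleolar RNA Snord67 held 89.1% of the sum of FPKM in GFP-positive cells. FPKM of genes this short depend strongly on the assumed fragment length.

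Sequencing depth per library is unknown. FPKM times length was examined in genes with 1 annotated transcript, for steps of 1 fragment. The step was set to the median of the products under 0.1, with length in kilobases. Among values under 20 such steps, 31.6% lay within 0.1 of a whole step in GFP-negative cells and 24.4% in GFP-positive cells. An even spread gives 20%, but taking the step from the same values can raise the share. No depth and no counting interval could be taken from this. Coordinates are those of the table on mm10, with starts raised by 1 because the table counts from 0. Of 20674 symbols found in RefSeq for GRCm38.p6, 99.1% had an interval that overlapped the RefSeq gene, and 10017 starts were equal after adding 1 against 652 as written. Identifiers and gene types came from GENCODE M21, matched by symbol.

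Before the data were examined, comparisons within ileum, within colon, across both regions with limma, and between colonic and ileal glia had been planned, with a correlation of the sort effect between regions. Because both regions stand in 1 column per sort population, none of these was made. The comparison made was GFP-positive against GFP-negative cells over both regions. The difference was log2(FPKM + 1) in GFP-positive minus GFP-negative cells, which understates the change of genes with low values. Genes were counted by the planned size rule of at least 4-fold on this scale, which is no test. The authors' calls are copied from their table. "Rose" and "fell" are used only for genes they called.

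Lists of marker and pathway genes were fixed before the data were examined. They covered the sorting gene, enteric glial markers, neural crest and glial transcription factors, Schwann cell, myelin, astrocyte and oligodendrocyte precursor genes, and enteric neurons. They also covered gut, ileal and colonic epithelium, smooth muscle, fibroblasts, interstitial cells of Cajal, endothelium, mesothelium, macrophages and dendritic cells, lymphocytes and plasma cells, and red blood cells. The others were antigen presentation, immediate early and heat shock genes, cell cycle, cholesterol synthesis, neurotrophic ligands, neurotransmitter and purine receptors, connexins and pannexins, the Notch pathway, the extracellular matrix of nerve sheath, 2 groups of Hox genes, sex-linked genes and ribosomal proteins. The 32 lists held 407 genes of the table, 16 of them in more than 1 list. A list's median difference was placed among those of 10000 random lists of the same size, matched on mean FPKM in 20 bins, as a description of these libraries. Members are called "adjusted over the list alone" when the authors' p-values of the tested members, adjusted by Benjamini-Hochberg within the list, were under 0.05.

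The named genes followed the rule fixed beforehand, applied to the pooled columns: among genes with at least 10 FPKM in either column, the 10 highest and 10 lowest differences, and from each list up to 4 members with the largest absolute differences among those with at least 5 FPKM. Gfap, S100b, Sox10, Mbp, Mpz, Aqp4 and Aldh1l1 were named whatever their value. The authors' 28 called genes, and other members given beside these, were named after the values were seen.

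The alternatives were pseudocounts of 0.1 and 5, a mean of at least 1 FPKM, 2-fold and 8-fold limits, and scaling GFP-positive values to the upper quartile of GFP-negative values. The scaling used genes with a mean of at least 1 FPKM and raised all GFP-positive values by 0.27 on the log2 scale. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures. The size rule was tested on simulated data for 23284 genes of which 200 were changed, with noise of 0.3 (SD, log2) added to both columns. It found 100% of genes raised 8-fold, 92% of genes lowered 8-fold, and 0% of genes raised 2-fold and 4% of those lowered 2-fold. No unchanged gene passed, a share of 0%. Genes at 0 stayed at 0 in the simulation, and changes were planted only in genes with at least 10 FPKM. The noise of the real libraries is unknown, so this share is not a rate of false passes in the data. Of 200 lists of unchanged genes, 4.5% fell outside the central 95% of random lists.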

Results

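Gene expression was compared between GFP-positive and GFP-negative cells of the mouse ileum and colon. GFP marked cells that express Plp1, which the study assigned to enteric glia, the glial cells of the nervous system of the gut. GFP-negative cells were the remaining cells of the same tissue. There were 4 libraries, 1 per gut region and sort population, each pooled from 3 animals, and the deposited values combine the regions into 1 value per sort population. No value has a replicate or an error of its own, and the depth of the libraries is unknown. Of 23284 genes, 10451 had at least 1 FPKM in GFP-positive cells and 11601 in GFP-negative cells.

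The comparison asked how the transcripts of Plp1-expressing glia differ from those of the other cells of the gut. Plp1 itself, used for the sort, stood at 2.46 FPKM in GFP-negative and 479 FPKM in GFP-positive cells. It rose 195-fold in the authors' deposited table (log2 fold change 7.61, q = 0.0118). The gene lies on chromosome X from 136822836 to 136837742 (mm10) and ranked 77 among all genes in GFP-positive cells. Sox10, a transcription factor of neural crest and glia, stood at 0.0206 and 42.1 FPKM. In the authors' deposited table Sox10 (chromosome 15, 79154913 to 79164490) rose 2041-fold with q = 0.0362. Foxd3, another neural crest transcription factor, stood at 0.0607 and 22.1 FPKM, and rose by 8.51 on the log2 scale in the authors' deposited table with q = 0.0207. The cadherin Cdh19 stood at 0.336 and 42.1 FPKM, and rose by 6.97 in the same authors' deposited table with q = 0.0118.

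The authors' deposited table called 28 genes at q under 0.05, of which 21 rose and 7 fell in GFP-positive cells. In the authors' deposited table the folds of the risen genes ran from 30.3 to 2041 and those of the fallen genes from 61.5 to 327. Among the risen genes were 3 voltage-gated potassium channels. Kcna1 (chromosome 6, 126636463 to 126645801) stood at 0.605 and 116 FPKM, with q = 0.00722 in the authors' deposited table. Kcna2 stood at 0.734 and 55.7 FPKM and Kcna6 at 0.204 and 34.0 FPKM. Gjc3, a connexin of myelinating glia, stood at 0.0873 and 22.6 FPKM (chromosome 5, 137953809 to 137962959). Gpr37l1, a G protein-coupled receptor, stood at 0.158 and 41.0 FPKM. Sostdc1, a secreted inhibitor of BMP and Wnt signals, stood at 1.60 and 198 FPKM. The kainate receptor subunit Grik3 stood at 0.0611 and 27.0 FPKM, and the tachykinin receptor Tacr3 rose 221-fold in the authors' deposited table. The collagens Col20a1 and Col28a1 stood at 74.3 and 13.1 FPKM in GFP-positive cells, against 0.310 and 0.157 FPKM. The other risen genes were Sema3e, Ptprz1, Nell2, Slc35f1, Fign, Wdr86 and Zfp451.

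Of the 7 genes that fell, 0610010O12Rik (chromosome 18, 36348624 to 36393370) stood at 383 FPKM in GFP-negative and 1.75 FPKM in GFP-positive cells, with q = 0.00722 in the authors' deposited table. Ppp1r8, a regulatory subunit of protein phosphatase 1, stood at 271 and 2.71 FPKM (chromosome 4, 132826925 to 132843169). H2-DMb2, which helps load peptides onto class II molecules, stood at 55.1 and 0.169 FPKM. The other genes that fell were Arhgdib, an inhibitor of Rho proteins in blood cells, with Msrb2, Spryd3 and Slco4a1. All 27 called genes with a match in GENCODE M21 were protein-coding, and 0610010O12Rik had no match. At an unadjusted p under 0.05, the authors' deposited table held 1248 of 12803 tested genes, or 9.75% where chance gives 5%. Of these, 462 were higher and 786 lower in GFP-positive cells. Adjusting the authors' p-values over the genes tested in their deposited table gave 34 higher and 13 lower genes in place of 21 and 7, with all 28 calls included.

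By the size rule of at least 4-fold, 627 genes were higher and 709 lower in GFP-positive cells, so 46.9% of these were higher. With upper quartile scaling the split was 766 higher and 525 lower, or 59.3% higher. The higher share was 67.8% with a pseudocount of 5 and 68.0% at 8-fold. It was 33.8% with a pseudocount of 0.1 and 31.4% at 2-fold, so the prevailing direction depended on the setting. The median difference of the 11558 genes with a mean of at least 1 FPKM was -0.41 on the log2 scale. Values are given without the scaling, which adds 0.27 to each difference at high values. The highest differences by size went to Snord67, Wasf1, Plp1, Spsb4, 9130404H23Rik, Cdkal1, Gpr124, Snora34, Trim44 and Tpk1, of which the authors called Plp1. Wasf1, a regulator of actin, stood at 0.624 and 313 FPKM, with p = 6.72e-05 and q = 0.0665 in the authors' deposited table. Spsb4 stood at 1.17 and 267 FPKM. Snord67 was listed at 0 and 2167030 FPKM and Snora34 at 0 and 86.3 FPKM, with p = 0.452 and p = 0.458 in the authors' deposited table. Their 0 in GFP-negative cells can be a failed estimate, so the place of these 2 genes is uncertain. The lowest differences on this scale were listed for Malat1, Rnu11, 0610010O12Rik, Snora21, Chad, the joint row of Ccl21a and Gm1987, Ppp1r8, Gm6793, Snora24 and H2-DMb2, of which the authors tested 7 and called 3. Malat1, marked as high data, and Snora24 and the joint row, marked as low data, were not tested. Malat1, Rnu11, Snora21 and Snora24 were listed at 0 FPKM in GFP-positive cells, where a 0 can be a failed estimate, so their place in this ranking is uncertain. The 20 genes included 5 small RNA genes.

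**Figure D1:**
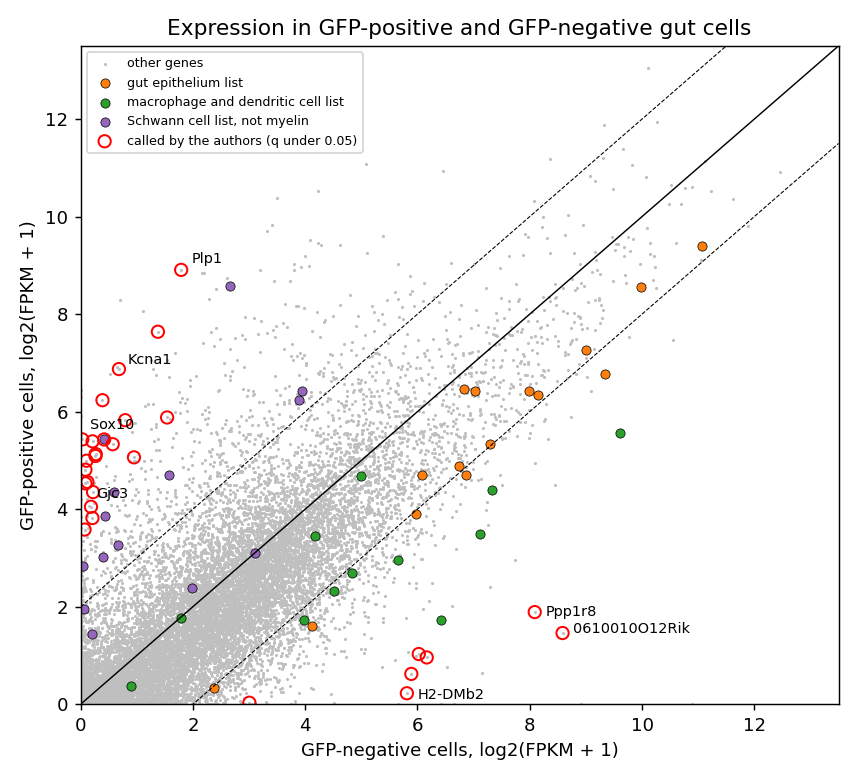
Expression of each gene in GFP-negative cells (horizontal axis) and GFP-positive cells (vertical axis), both as log2(FPKM + 1); dashed lines mark 4-fold differences and red circles the 28 genes the authors called. Plp1 and most Schwann cell genes lie above the diagonal, most gut epithelium and macrophage genes lie below it, and Snord67 (2167030 FPKM) lies beyond the axis.

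Genes of enteric glia and of Schwann cells, the glia of peripheral nerves, were higher in GFP-positive cells. Of 11 enteric glial markers, 7 were at least 4-fold higher and none at least 4-fold lower, and the median difference of 3.12 exceeded 100% of random lists. The authors called 3 of them, and 5 passed when adjusted over the list alone. Fabp7, a fatty acid binding protein of glia, stood at 0.786 and 33.6 FPKM. S100b was listed at 0 and 17.4 FPKM, and Gfap stood at 0.0216 and 5.15 FPKM, with p = 0.0428 and p = 0.0672 in the authors' deposited table. Of 14 Schwann cell genes outside myelin, 10 were at least 4-fold higher, with a median of 2.61 above 100% of random lists, and 11 passed when adjusted over the list alone. Scn7a, a sodium channel, stood at 5.29 and 379 FPKM, Gfra3 at 0.509 and 19.3 FPKM, and Cadm4 at 0.344 and 13.6 FPKM. The 18 neural crest and glial transcription factors had a median of 0.68, above 99.99% of random lists, and of 1.39 over members with at least 1 FPKM. Beyond Sox10 and Foxd3, Nfib stood at 8.52 and 72.2 FPKM and Zeb2 at 22.4 and 102 FPKM, and neither passed over the list alone.

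Of 21 myelin genes, 5 were at least 4-fold higher and 1 at least 4-fold lower, and 9 had less than 1 FPKM in both columns. The median was 0.01, above 99.29% of random lists, and lay at the 97.02 percentile with upper quartile scaling. Over the 12 members with at least 1 FPKM in either column the median was 1.65, above 100% of random lists. Gjc3 was called by the authors, and 3 members passed when adjusted over the list alone. Mbp, myelin basic protein, stood at 3.48 and 60.7 FPKM, Mal at 0.523 and 24.6 FPKM, and Plekhb1 at 1.53 and 107 FPKM. Mpz, the main protein of peripheral myelin, was listed at 0 and 2.21 FPKM, with p = 0.104 in the authors' deposited table. Mag, Mog, Mobp, Opalin and Pmp2 were listed at 0 in both columns.

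Genes of astrocytes, glia of the brain, went both ways. Of 20 members, 3 were at least 4-fold higher and none at least 4-fold lower, with 7 at least 2-fold lower. The median of -0.21 exceeded 33.8% of random lists, and no member passed, whether adjusted over all genes or over the list alone. Entpd2, an enzyme that breaks down extracellular ATP, stood at 6.89 and 85.6 FPKM, and Atp1b2 at 6.20 and 36.1 FPKM. Aldh1l1 stood at 7.39 and 1.18 FPKM, and Aqp4, a water channel, at 66.0 and 27.3 FPKM. The oligodendrocyte precursor list of 11 genes had a median of 0, with 2 members at least 2-fold higher and none called. Vcan stood at 23.8 and 71.5 FPKM and Pdgfra at 20.5 and 16.3 FPKM.

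Genes of other cell types also differed between the sort populations. Of 22 enteric neuron genes, 9 were at least 4-fold higher and 1 at least 4-fold lower in GFP-positive cells, and the median of 1.52 exceeded 100% of random lists. The authors called none of them, and 6 higher and 1 lower member passed when adjusted over the list alone. Scg2 stood at 3.03 and 48.9 FPKM, Snap25, a protein of synaptic release, at 2.91 and 46.7 FPKM, the neuropeptide Vip at 1.04 and 19.5 FPKM and Hand2 at 1.15 and 14.1 FPKM. Chgb was lower, at 33.7 and 4.78 FPKM. Of 12 fibroblast genes, 4 were at least 4-fold higher, the median of 1.53 exceeded 99.11% of random lists and none passed when adjusted over the list alone. Col3a1 stood at 643 and 3761 FPKM, Col1a2 at 328 and 2313 FPKM, and Mfap5 at 43.1 and 313 FPKM.

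Most epithelial genes were lower in GFP-positive cells. Of 15 gut epithelium genes measured, 13 were at least 2-fold lower, with a median of -1.81 that exceeded 0% of random lists. The keratin Krt19 stood at 647 and 108 FPKM, Krt18 at 115 and 25.1 FPKM, and Chga at 16.5 and 2.02 FPKM. All 15 ileal epithelium genes were at least 2-fold lower, with a median of -1.80 that exceeded 0% of random lists. Apoa1 stood at 542 and 84.4 FPKM and Lyz1 at 254 and 42.8 FPKM. Fabp2, a fatty acid binding protein of enterocytes, stood at 3772 FPKM and still at 895 FPKM in GFP-positive cells. Of 13 colonic epithelium genes measured, 9 were at least 2-fold lower, and the median of -1.34 exceeded 0.50% of random lists. Car4 stood at 39.2 and 5.85 FPKM and Slc26a3 at 57.2 and 12.8 FPKM, while Retnlb was higher at 1074 and 1799.9 FPKM. The authors called no member of these 3 lists, and none passed when adjusted over the list alone.

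Macrophage and dendritic cell genes had the lowest median of the lists, -2.22, which exceeded 0% of random lists. Of 12 members, 8 were at least 4-fold lower, and 5 passed when adjusted over the list alone. The other 4 were within 2-fold, among them Mrc1 at 30.9 and 24.6 FPKM and C1qa at 17.0 and 9.94 FPKM. Emr1, the macrophage marker F4/80, stood at 84.2 and 2.31 FPKM with q = 0.0522 in the authors' deposited table. Lyz2 stood at 781 and 46.5 FPKM and C1qb at 137 and 10.2 FPKM. Antigen presentation genes had a median of -1.22 that exceeded 0.65% of random lists, with 3 of 9 members lower when adjusted over the list alone. With a pseudocount of 0.1 their median was -3.19. H2-Ab1 stood at 152 and 11.8 FPKM and H2-Aa at 274 and 29.8 FPKM. The 11 lymphocyte and plasma cell genes measured had a median of -0.72, which exceeded 1.63% of random lists and 2.62% with upper quartile scaling. It exceeded 2.56% with a pseudocount of 0.1 and 4.60% with members of at least 1 FPKM. Igj stood at 13.8 and 2.14 FPKM and Ptprc at 8.81 and 1.36 FPKM.

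Of 11 smooth muscle genes, 8 were at least 2-fold lower, with a median of -1.35 that exceeded 0.72% of random lists. Tagln stood at 55.8 and 8.76 FPKM and Myh11 at 71.8 and 15.3 FPKM. The 5 genes of interstitial cells of Cajal, pacemaker cells of the gut, had a median of -1.57 that exceeded 0.93% of random lists. Kit stood at 12.8 and 0.709 FPKM and Thbs4 at 21.6 and 3.90 FPKM, and both passed over the list alone. The 12 endothelium genes had a median of -0.89, which exceeded 2.89% of random lists and 2.24% with upper quartile scaling. It was -2.13 at the 0.36 percentile with a pseudocount of 0.1, and -1.38 at 0.58 over members with at least 1 FPKM. Pecam1 stood at 7.73 and 1.25 FPKM, and Tek went the other way at 1.56 and 11.9 FPKM. The 6 mesothelium genes had a median of -0.33 that exceeded 0.41% of random lists, and of -1.76 with a pseudocount of 0.1. Only 2 of them had at least 1 FPKM in either column. The 4 rows of red blood cell genes had a median of 0.05, above 84.07% of random lists, and the joint row of Hba-a1 and Hba-a2 stood at 12.2 and 11.5 FPKM.

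**Figure D2:**
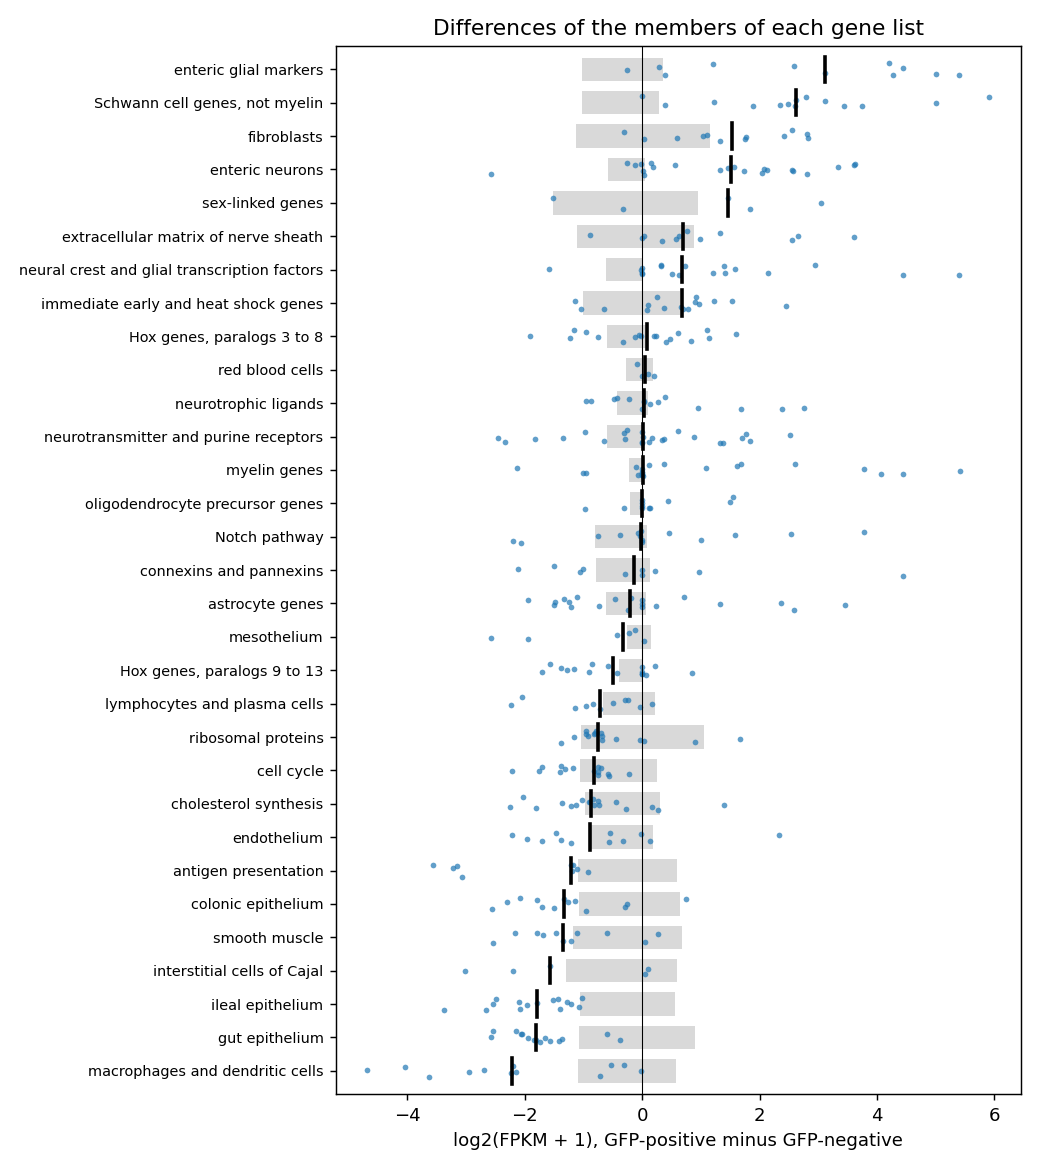
Difference of each list member, as log2(FPKM + 1) in GFP-positive minus GFP-negative cells, on the horizontal axis; dots are genes, black bars are list medians and grey bars hold the central 95% of medians of 10000 random lists. The medians run from -2.22 for macrophages and dendritic cells to 3.12 for enteric glial markers.

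The 14 Notch pathway genes had a median of -0.01 at the 81.78 percentile of random lists. With upper quartile scaling it became 0.16, at the 95.92 percentile. Heyl and Hey1, target genes of Notch, stood at 1.11 and 27.8 FPKM and at 0.536 and 7.93 FPKM. Notch3 stood at 5.14 and 0.333 FPKM, and Lfng was lower too. These 4 genes passed when adjusted over the list alone. The 10 connexins and pannexins had a median of -0.15 at the 51.65 percentile, and of -1.01 at the 10.29 percentile over members with at least 1 FPKM. Gjc3 was the member called by the authors, and Gja4 stood at 7.60 and 0.979 FPKM. The 25 neurotransmitter and purine receptors had a median of 0.02 at the 99.03 percentile, and at 95.67 with upper quartile scaling. The sphingosine receptor S1pr3 stood at 1.91 and 15.7 FPKM, and the purine receptor P2ry4 at 12.8 and 1.53 FPKM. The 15 neurotrophic ligands had a median of 0.04 at the 94.57 percentile, and at 97.65 with upper quartile scaling. Over members with at least 1 FPKM the median was 0.94 at the 99.13 percentile. Pdgfa stood at 23.3 and 125 FPKM, and Cntf was listed at 0 and 5.74 FPKM. No receptor or ligand passed over its list alone.

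The 12 genes of nerve sheath matrix had a median of 0.70 at the 95.2 percentile. Col28a1 was called by the authors, Col18a1 stood at 9.21 and 63.2 FPKM, and Nid1 at 57.5 and 341 FPKM. Immediate early and heat shock genes, which respond to handling of cells, had a median of 0.68 at the 97.79 percentile, and at 97.14 with upper quartile scaling. Of 16 members, 3 were at least 2-fold higher, 2 at least 2-fold lower and 11 within 2-fold. Hspa1a stood at 95.9 and 526 FPKM and Egr1 at 76.4 and 179 FPKM, while Hspa1b stood at 125 and 149 FPKM. The 15 cell cycle genes had a median of -0.82 at the 11.32 percentile, with Mcm5 at 8.61 and 1.06 FPKM and Top2a at 38.8 and 14.3 FPKM. The 18 cholesterol synthesis genes had a median of -0.87 at the 5.63 percentile, with Dhcr7 at 24.0 and 4.26 FPKM. The 16 ribosomal proteins had a median of -0.75 at the 9.62 percentile, with Rps6 at 282 and 125 FPKM and Rpl32 at 1238 and 3917 FPKM. No member of the last 4 lists passed when adjusted over the list alone.

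Hox genes, whose paralog groups are expressed along the body axis, were held in 2 lists. The 18 genes of paralogs 3 to 8 had a median of 0.09 at the 98.11 percentile, and the 16 genes of paralogs 9 to 13 a median of -0.50 at the 0.52 percentile. With a pseudocount of 0.1 or with members of at least 1 FPKM, the first list lay inside the central 95% of random lists, at the 95.57 and 97.00 percentiles. The second list lay at 2.34, outside the central 95%, and at 2.51, just inside it, in the same settings. Hoxb9 stood at 11.8 and 2.93 FPKM and Hoxb13 at 22.8 and 8.79 FPKM, and no Hox gene passed over its list alone. The 5 sex-linked genes had a median of 1.46 at the 99.21 percentile but went both ways. Kdm5d of the Y chromosome stood at 1.58 and 20.4 FPKM, Ddx3y at 12.4 and 3.66 FPKM, and Xist at 52.7 and 147 FPKM, and none passed over the list alone. The difference between the 2 Hox lists was not tested.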

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

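The adjustments over the genes of the table, the 0.1 limits on q and the last 2 settings of the size rule were chosen after seeing the data. Counts by the size rule depended on pseudocount and fold. They were 627 higher and 709 lower as reported, 1172 and 2294 with a pseudocount of 0.1, and 320 and 152 with a pseudocount of 5. They were 1590 and 3473 at 2-fold and 247 and 116 at 8-fold. The cause lies in the settings themselves, since a lower pseudocount or fold lets more genes with low values pass. The share of higher genes among them ran from 31.4% at 2-fold to 68.0% at 8-fold, so the prevailing direction depended on the setting. Requiring a mean of at least 1 FPKM tested nothing, since a gene at 4-fold with a pseudocount of 1 always has such a mean. Genes tested by the authors, above 0 in both columns and not small RNAs numbered 603 and 677, and those with an authors' p under 0.05 numbered 383 and 501. The authors' calls were 21 and 7 as deposited. They were 34 and 13 when adjusted over the table alone, 292 and 352 at a deposited q under 0.1, and 58 and 27 when adjusted over the table alone at 0.1. Of 31 list medians, 20 lay outside the central 95% of random lists. Of these, 18 also did with a pseudocount of 0.1, 16 with upper quartile scaling and 16 with members of at least 1 FPKM, where mesothelium had too few members for a median, and none of the 20 changed sign with the last 2 settings. With a pseudocount of 0.1, medians moved to 5.25 for enteric glial markers, 3.90 for Schwann cell genes, 2.69 for enteric neurons, -1.71 for lymphocytes and plasma cells, -1.76 for mesothelium and -3.19 for antigen presentation. Over members with at least 1 FPKM, they moved to -1.01 for connexins and pannexins and -1.15 for Hox paralogs 9 to 13. Of 44 named differences, 35 moved by over 0.58 with a pseudocount of 0.1. The scaling shifts them by at most 0.27. The settings chosen beforehand for ileum, colon, both regions, limma, the correlation between regions and colonic against ileal glia were not run, because the deposited columns combine the regions. No paired analysis was possible because the columns carry no replicate. Unknown depth limits all statements on genes near 0.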

Other observations

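The gene families and tests in this part were chosen after the values were seen. Values of 9 gene families named by symbol were computed over members with at least 1 FPKM in either column. Cell adhesion molecules of the nervous system had 10 of 14 members at least 4-fold higher in GFP-positive cells and a median of 2.55 above 100% of random lists, and the authors called none of them. Cadm3 stood at 1.47 and 41.1 FPKM in GFP-negative and GFP-positive cells, and Chl1 at 1.58 and 42.4 FPKM. Of these members, L1cam, Ncam1, Nrxn1, Cadm2 and Cadm4 also belong to the Schwann cell list. The 5 glutamate receptors had a median of 1.86 above 100% of random lists, with Gria3 at 1.36 and 12.5 FPKM and Grik2 at 0.0114 and 2.68 FPKM beside Grik3. The median was that of Grik2. The called Grik3 was known when the family was chosen, so this rank is no separate result. Gria1 of the same family went the other way, at 1.72 and 0.110 FPKM, and Grik5 stood at 1.05 and 1.74 FPKM. The 9 voltage-gated potassium channels had a median of 1.35 above 99.99% of random lists. They include the 3 called Kcna genes, known when the family was chosen, so this rank is no separate result. The median was that of Kcnh8, at 0.0215 and 1.61 FPKM, while Kcnq1 was lower at 7.79 and 1.09 FPKM. Semaphorins went both ways, with a median of -0.38 at the 52.96 percentile. Sema3d stood at 0.925 and 30.8 FPKM beside the called Sema3e, and Sema5a at 20.7 and 4.13 FPKM.

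Of 28 collagens, 10 were at least 4-fold higher and none 4-fold lower, with a median of 1.81 above 100% of random lists. They include the called Col20a1 and Col28a1, known when the family was chosen. The fibroblast list was higher as well, with a median of 1.53 at the 99.11 percentile, and some collagens and laminins belong to it or to the nerve sheath list. Col8a1 stood at 13.4 and 288 FPKM and Col14a1 at 12.6 and 167 FPKM. Of 11 laminins and nidogens, 3 were at least 4-fold higher, with a median of 0.76 at the 98.16 percentile, and the authors called 2 of the collagens and none of these. Lamb2 stood at 4.34 and 365 FPKM and Nid2 at 3.98 and 45.9 FPKM. Proteases of mast cells were lower, with 6 of 8 members at least 4-fold lower and a median of -3.07 that exceeded 0% of random lists, and none called. Mcpt1 and Mcpt2 stood at 56.0 and 62.0 FPKM in GFP-negative cells and at 1.11 and 0.986 FPKM in GFP-positive cells. Defensins of Paneth cells had a median of -1.92 at the 0.11 percentile, yet Defa3 stood at 121 and 146 FPKM. The 214 solute carriers had a median of -0.58 at the 2.04 percentile, and at 2.56 with upper quartile scaling. The somatostatin gene Sst was higher in GFP-positive cells, at 41.4 and 222 FPKM, with p = 0.0561 in the authors' deposited table. The 19 genes that pass only when the authors' p-values are adjusted over the table alone include Megf10, Gfra2, Cadm3, Lgi1 and Prnp, which are higher, and Mcpt1, Mcpt2, Lyz2 and Emr1, which are lower.

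Transcripts of enteric neurons were higher in GFP-positive cells. Enteroendocrine cells, hormone cells of the epithelium that share secretory genes with neurons, are argued against as their source. The median difference of 14 enteroendocrine markers was -2.10, which exceeded 0% of random lists, with Pyy at 347 and 21.5 FPKM and only Sst higher; 1 marker is in the neuron list and 1 in the gut epithelium list. Neurons or their fragments carried along in the sort may be a source. Of the 22 neuron genes, 59.1% were at least 2-fold higher, between limits of 80% and 50% set after the values were seen. These limits cannot decide it, because 8 members had less than 1 FPKM in both columns, where depth is unknown. Such members cannot reach 2-fold on the scale used. Of the 14 members with at least 1 FPKM in either column, 13 were at least 2-fold higher and Chgb was lower. Stmn2 stood at 1.29 and 6.66 FPKM and Uchl1 at 1.24 and 8.37 FPKM, against 2.91 and 46.7 FPKM for Snap25. Carry-over of neurons stays open. Expression of these genes by the glia themselves is a possible biological explanation, and it was not tested.

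Epithelial transcripts remained in GFP-positive cells: over 37 epithelial genes with at least 10 FPKM in GFP-negative cells, the median ratio was 29.9% of the GFP-negative level, against 14.7% over 10 macrophage genes. The difference of -1.02 on the log2 scale was above that of 0.29% of random divisions of the same genes. Carry-over of all GFP-negative cells in equal proportion would put both cell types at 1 ratio. The macrophage list was taken after the values were seen and had the lowest median of the lists, which this share does not allow for. Smooth muscle genes had a list median of -1.35, against -1.81, -1.80 and -1.34 for the 3 epithelial lists. The smooth muscle values therefore do not speak against equal carry-over. Mast cell proteases, also taken after the values were seen, had 6 of 8 members at least 4-fold lower and a median of -3.07. Equal carry-over would hold them near the medians of the epithelial lists. The macrophage and mast cell values argue against equal carry-over as the only source of the epithelial transcripts. The 3 epithelial lists had median log2 ratios within 0.22 of each other, a range above that of 14.22% of random divisions of their genes. Epithelial cells or their RNA as 1 source would give a range within 0.58. That limit was passed by 15.43% of those divisions. It was passed by 61.67% of random triples of lists matched on mean FPKM, so 38.33% would meet it by chance. Ileal and colonic cells were in separate libraries that the columns combine, so the range cannot show 1 source for both. Of the 37 genes, 30 lay within 2-fold of the median ratio. The others ran from 6.08% for Apoc3 to 168% for Retnlb, which an epithelial source at 1 ratio does not account for. No biological explanation was tested.

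For the called genes, the deposited q-values were higher than an adjustment over the table's own tests gives. Further down the ranking they were lower, as for Snap25, at 0.0665 against 0.105. At a limit of 0.1, 292 higher and 352 lower genes passed by the deposited q. Over the table's own tests 58 and 27 did. Multiplying q by the rank of p and dividing by p gave 36017 tests for the last gene of each of the 12 runs of equal q among the called genes, from 36016.8 to 36017.2, where the table holds 12803. This is consistent with an adjustment over 23214 further tests that are not rows of the table. Of these, 0 would have a p up to 6.07e-05, 18.9% a p up to 0.01, 47.1% up to 0.05 and 100% up to 0.5, against 34 tests, 3.14%, 9.75% and 54.8% of those in the table. What was tested there, with no p above 0.5, stays open, and no biological explanation was tested.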
